A study of Mus musculus and Homo sapiens with 45 samples.

How the data were processed

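The series holds low-input ribosome profiling of neonatal mouse forebrain, of callosal (CPN) and subcerebral (SCPN) projection neurons from mouse cortex, and of HEK293T cells, an established human kidney-derived line. Footprint libraries were made from RNA that ribosomes protected from RNase I. RNA libraries were made from extracted RNA that was cut either with RNase I or by alkaline hydrolysis, with fragments of 20 to 60 nt taken after the latter. Per the labels, CPN were marked by electroporation of a membrane-bound tdTomato at embryonic day 14.5 or 15.5 in CD-1 mice, and cycloheximide at 100 ug/mL was in all of their buffers. SCPN were marked by tracer injected into the cerebral peduncle at postnatal day (P) 1 in a B6SJL by CD-1 cross, and their cycloheximide was added only after the sort. Both were dissociated with papain and sorted by fluorescence. The 2 cell types therefore differed in label, strain and drug timing as well as in identity.

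For each gene, the authors deposited raw counts of reads in its coding sequence, its 5' UTR and its 3' UTR, and counts of reads by length and annotation class. Their processing notes name UMI-tools, cutadapt 2.8, STAR 2.6 and featureCounts of Subread, with the builds mm10 and GRCm38, and do not give the order or the role of each. The deposited annotation of coding lengths in nt came from featureCounts 1.5.1 with release 95, per the file headers. Open reading frames (ORFs) were called by the authors with RiboCode, whose version is not stated. Each deposited ORF table gives P-site counts per frame, a length in nt and a combined p-value, all under 0.05. Per the labels, 1 table pooled the CPN footprints of the pilot and the hemispheres. The labels do not say which libraries the other 2 tables, named for CPN and SCPN, had pooled.

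Values of 23 libraries were used. The count columns of 16 further CPN and SCPN libraries and of the 6 HEK293T libraries carry codes or names that no label pairs with a sample, so 76 value columns and 16 codes of a length table were left out. The comparisons of CPN with SCPN in footprints, RNA, translation efficiency, 5' UTR counts, region shares and lengths that were fixed for those libraries, and that of cell numbers in HEK293T, were therefore not run. No gene of the mitochondrial chromosome was in the count tables, so leaving these genes out changed nothing and was not run. Of 20866 gene identifiers in each count table, 20841 matched a symbol, and 28 symbols belonged to more than 1 identifier.

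Coding counts per library ranged from 43277 to 1464371. Shares of counts in single libraries carry Wilson 95% intervals and ratios of 1 gene between 2 libraries carry 95% intervals from the binomial distribution, given at 10 or more counts in the 2 libraries together. These cover counting error only. The most abundant gene took at most 1.03% of coding counts.

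Footprints and RNA of the 5 hemispheres were compared with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F-tests on coding counts, with TMM factors, filterByExpr, a mean per group and Benjamini-Hochberg adjusted p under 0.05. Fold changes of coding counts are relative to the average gene. Gene lists were fixed before the data were examined and tested by camera of limma 3.58.1 with a preset correlation of 0.01 when at least 5 members were tested, with adjustment over lists. An estimated correlation and fry, which tests whether a list's genes move 1 way on balance, stood beside it. Shares of regions and read lengths were compared by exact two-sided permutation tests over 252 assignments, whose smallest p is 0.00794. Groups without replicates were described without a test. For pairs of single libraries, the median log2 ratio of a list over genes with a mean of 10 or more CPM (counts scaled to the same library total), with 0.5 counts added and each ratio taken relative to the median gene, was placed among 10000 random lists of the same size and like abundance (seed 20240501). Lists of striatal markers were added after the values of the SCPN library were seen.

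Upstream ORFs were those that the authors typed uORF or Overlap_uORF. Their share in each list was compared with other genes that had a called coding ORF by two-sided Fisher's exact tests, adjusted over the lists. The set of genes with an upstream ORF was tested by camera on the hemisphere contrast. A fit of 5' UTR counts in the hemispheres, on the library sizes and factors of the coding counts, was added after the data were seen. Its fold changes are relative to coding counts and not to the average 5' UTR.

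The rule for named genes was fixed at the same time as the lists. It took the 10 largest fold changes in each direction among called genes with a mean CPM of 10 or more and no overlap between groups, every called CPN or SCPN marker, and up to 4 members of each other list by adjusted p. Predicted genes without a symbol, pseudogenes and histone genes stayed out of the first part. For upstream ORFs it took up to 4 genes per list by the authors' p. Genes named from single libraries, and those of the 5' UTR fit, were chosen after their values were seen. Some genes that would be named are not reported here.

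The titles give each hemisphere a footprint and an RNA library with the same number. Across genes, residuals of same-numbered libraries correlated at 0.0504 to 0.591, against a median of -0.125 for other pairs, and 4 of 5 hemispheres matched their own number best. With hemisphere number as a replicate block, 1559 genes were called. The labels do not say that hemispheres or libraries came from separate animals, so the p-values may measure technical spread in part. Among the 20 pairs of hemisphere libraries of the same kind, chi-square per degree of freedom was 1.83 to 14.0, so none of these held the same counts; other pairs were not compared.

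Steps were tested on simulated data of the same size. In 4027 simulated genes of the hemisphere coding comparison, 2.33% of genes changed 1.5-fold were recovered, 31.0% at 2-fold, 94.9% at 3-fold and 97.5% at 4-fold. Of 94 calls, 4 were unchanged genes. In 542 simulated genes of the 5' UTR comparison, 10.9%, 38.1%, 78.4% and 97.1% were recovered at these folds. A planted list was called by camera and 0 of 20 unchanged lists were. Of 200 unchanged lists in a pair of libraries, 4.5% fell outside the 95% range, and 3.8% of 500 unchanged lists of upstream ORFs had p under 0.05. Simulated genes varied independently of each other, and hemispheres were not paired. False calls of lists whose genes vary together were therefore not measured by these simulations.

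Alternatives covered DESeq2 size factors and upper-quartile factors, other filters, DESeq2 1.42.0 in place of edgeR, a 1.5-fold threshold test, each library left out in turn, the replicate block, other length windows, other count minimums for correlations, and stricter or separate upstream ORF types. Removal of the trend with coding length by a loess curve, omission of both libraries of hemisphere 3 and several tests of upstream ORF genes were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 served the remaining steps.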

Results

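Ribosome footprints and RNA fragments were counted per gene in 23 mouse libraries. P4 forebrain gave 3 libraries, with coding counts of 319554 for footprints from lysate holding 30 ng of RNA, 304977 for footprints from a bulk lysate and 123761 for extracted RNA cut with RNase I. P5 forebrain was digested at 2.5, 12.5, 62.5 and 312.5 U/mL of RNase I, with 138837, 277670, 203130 and 210241 coding counts, beside extracted RNA with 43277. Pilot footprints at P3 came from callosal neurons (CPN), which join the cortical hemispheres, and from subcerebral neurons (SCPN), which project to brainstem and spinal cord. The CPN libraries held 1033896 coding counts (50k cells, 12.5 U/mL), 748931 (50k, 2.5 U/mL) and 305891 (17k, 12.5 U/mL), the SCPN library (50k, 12.5 U/mL) held 459413, and alkaline-cut RNA of P3 cortex held 561327. At P4, CPN of 5 hemispheres were each divided between a footprint library of 2.5k to 20.8k cells and an RNA library of 0.8k to 6.2k cells. Footprint libraries of hemispheres 1 to 5 held 1464371, 355192, 106890, 136223 and 370426 coding counts, and their RNA libraries held 308118, 187134, 145139, 119658 and 164187. The hemispheres were the comparison with replicates (n = 5 per group), and all other groups had 1 library, apart from CPN at 12.5 U/mL in the pilot, whose 2 libraries differed in cell number.

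The first comparison asked whether 30 ng of forebrain gives the footprints of a bulk preparation. Synaptophysin (Syp), a synaptic vesicle protein, had 369 footprints in the 30 ng library against 46 reads in extracted RNA, a log2 ratio of 1.83 (95% interval 1.40 to 2.32), and 2.08 (1.65 to 2.57) in the bulk library. Eif4g2, a translation initiation factor, was lower in footprints, at -1.70 (-1.99 to -1.41) with 30 ng and -1.80 (-2.11 to -1.50) in bulk. Respiratory chain genes, which encode mitochondrial oxidative phosphorylation, had a median log2 ratio of 1.12 with 30 ng, with 72 of 76 members higher, and 1.14 in bulk, with 65 of 75 higher, each above all random lists. Chromatin regulators had medians of -1.13 and -1.17, with 30 and 28 of 33 members lower, each below all random lists. Astrocyte markers, at 1.15 and 1.04, and heat shock chaperones, at 1.11 and 1.17, lay above the 95% range of random lists in both. Postsynaptic genes lay below it in bulk alone (-0.34, and -0.23 with 30 ng), and no other fixed list left it. Across genes also tested in the hemispheres, both ratios fell with coding length (Spearman's rho -0.554 with 30 ng, -0.495 in bulk). Random lists were matched on abundance and not on length, so these list medians cannot be told apart from that trend.

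Between the 30 ng and the bulk footprints, ribosomal protein genes had a median log2 ratio of 0.39 (99.5 percentile) and postsynaptic genes one of 0.16 (99.7 percentile), and respiratory chain genes one of -0.00. Coding sequence took 76.9% (76.8 to 77.1) of region counts with 30 ng and 81.6% (81.5 to 81.7) in bulk, against 48.9% (48.7 to 49.1) in extracted RNA. Reads of 28 to 32 nt made up 33.1% with 30 ng, whose commonest length was 33 nt, and 87.7% in bulk, where it was 28 nt. Counts of the 30 ng and bulk footprints correlated across 11181 genes at r = 0.903, and those of 30 ng footprints and extracted RNA at 0.785 across 10389 genes, which are not independent replicates. Both forebrain ratios share 1 RNA library, and the RNase doses of the 30 ng and bulk digests differed (2.5 and 2500 U/mL).

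**Figure D1:**
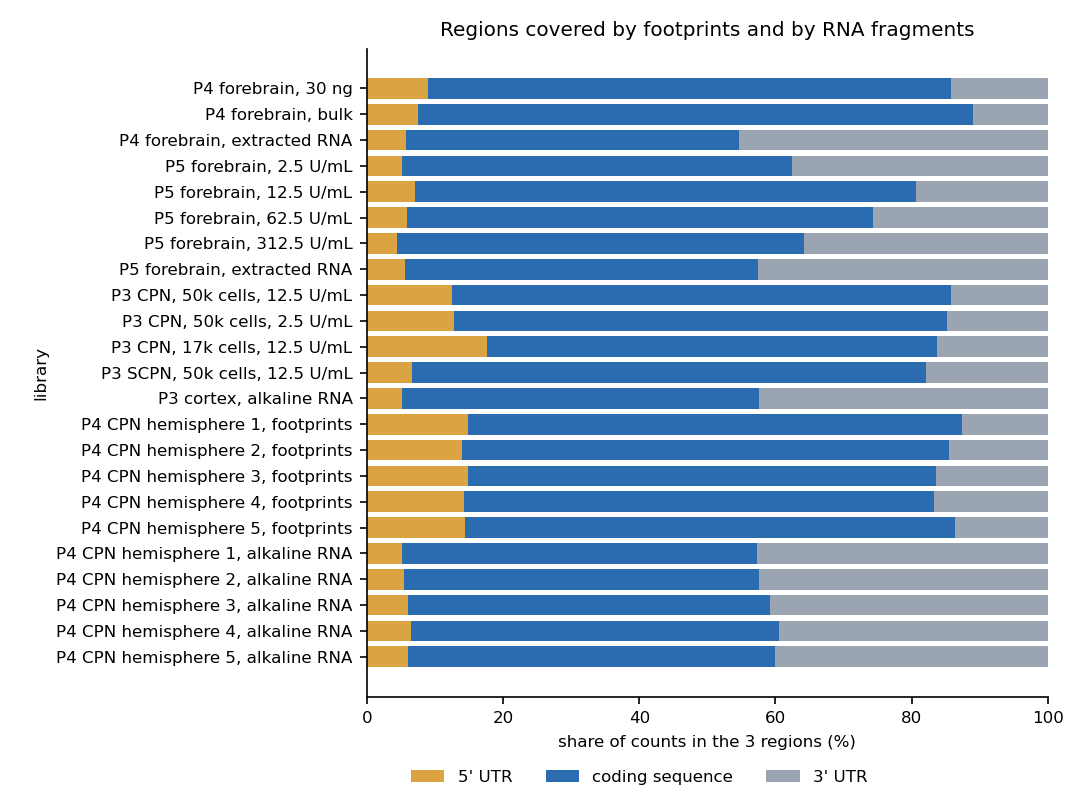
Share of region counts (%) in 5' UTR, coding sequence and 3' UTR for each of the 23 libraries, 1 bar per library. Footprint bars of the hemispheres hold 70.8% coding counts on average and their RNA bars 53.2%.

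The titration asked which RNase I dose leaves footprints at 30 ng of P5 forebrain. Among genes picked after their values were seen, at 312.5 against 12.5 U/mL, Tubb3, a neuronal tubulin, had a log2 ratio of -1.19 (-1.36 to -1.02), Tubb2a one of -1.40 (-1.61 to -1.19) and Syp one of -1.28 (-1.62 to -0.97). Setd5 was at 1.53 (0.80 to 2.34) and Kmt2a, which methylates histone H3, at 1.15 (0.61 to 1.71). By list, neuronal cytoskeleton (-0.82), presynaptic (-0.68), cholesterol synthesis (-0.69) and respiratory chain (-0.44) medians lay under the 2.5 percentile of random lists, chromatin regulators (0.68) lay above all of them and endothelial markers (1.14) at the 99.4 percentile. Against the extracted RNA of the same set, respiratory chain genes stood at 1.16 with 12.5 U/mL and 0.61 with 312.5 U/mL, and chromatin regulators at -0.57 and 0.06. The lowest dose differed from 12.5 U/mL in the same direction for some of these lists, at -0.82 for neuronal cytoskeleton, -0.54 for respiratory chain, -0.60 for cholesterol synthesis and 0.62 for chromatin regulators, each outside random lists, with presynaptic genes (-0.33) and endothelial markers (0.12) within them. It also differed in SCPN markers (-0.75) and ribosomal protein genes (0.46), which at 312.5 U/mL were within them (-0.37 and 0.27).

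Coding sequence took 57.4% (57.2 to 57.6), 73.7% (73.5 to 73.8), 68.6% (68.4 to 68.7) and 59.7% (59.6 to 59.9) of region counts from the lowest to the highest dose, against 52.0% (51.7 to 52.3) in extracted RNA. Reads of 28 to 32 nt made up 38.96%, 82.5%, 67.6% and 38.1%, against 16.9% in extracted RNA. The commonest length was 31, 30, 29 and 28 nt from the lowest to the highest dose. No test between doses was made, since each had 1 library. The 30 ng library of P4 forebrain had the same input and RNase dose as the lowest dose here. Coding sequence took 76.9% (76.8 to 77.1) of its region counts, against 57.4%. Its reads of 28 to 32 nt made up 33.1%, against 38.96%. Coding shares of single libraries therefore cannot tell an effect of dose apart from other differences between libraries, and the intervals cover counting error only.

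**Figure D2:**
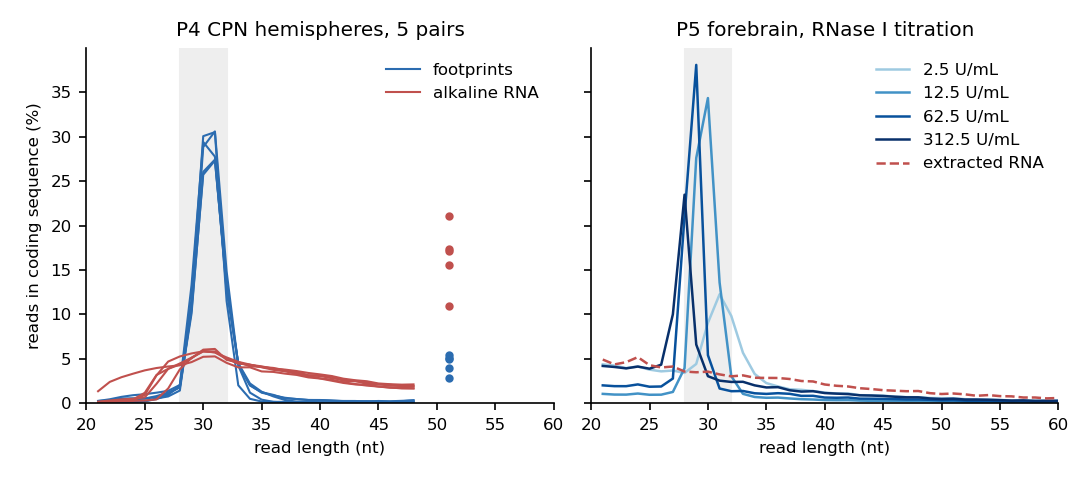
Reads in coding sequence (%) by read length (nt) for 5 footprint and 5 RNA libraries of the hemispheres (left, where points at 51 nt are reads of full length) and for the 5 titration libraries (right), with 28 to 32 nt shaded. Footprints of the hemispheres peak at 30 or 31 nt, and titration peaks move from 31 nt at 2.5 U/mL to 28 nt at 312.5 U/mL.

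The pilot asked whether footprints of sorted neurons carry the identity of their cell type. Bcl11b, a transcription factor of subcerebral neurons, had 338 counts in SCPN against 71 in CPN with 50k cells at 12.5 U/mL, a log2 ratio of 3.45 (3.09 to 3.85), and Crym, a cytosolic thyroid hormone binding protein, had 92 against 18, at 3.53 (2.82 to 4.38). Cux2, a transcription factor of upper-layer neurons, was lower in SCPN at -2.65 (-3.56 to -1.94). SCPN markers had a median of 1.32, with 11 of 14 higher, and CPN markers one of -0.88, with 20 of 24 lower, outside all random lists in both cases. Against the 17k and the 2.5 U/mL CPN libraries the SCPN marker medians were 1.17 and 1.34 and the CPN marker medians -0.84 and -1.09. Bcl11b is also expressed by striatal projection neurons, whose markers, a list added after the values were seen, stood higher in SCPN than the SCPN markers, at a median of 2.99 with 16 of 16 higher.

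Other lists parted the pilot libraries too. Oligodendrocyte lineage markers were lower in SCPN, at -2.49, -2.65 and -2.44 against the 3 CPN libraries, with no member higher, and Pdgfra, a receptor of oligodendrocyte precursors, had 17 counts against 328. Progenitor markers (-1.08), ribosomal proteins (-0.79) and respiratory chain genes (-0.73) were also under the range of random lists. Microglia markers (0.95), axon growth and guidance genes (0.49), postsynaptic genes (0.38) and immediate early genes (0.77, but 0.06 against the 17k library) were above it. Interneuron markers were within it at -0.10, but at -1.09 against the 17k library. Corticothalamic markers (0.49), astrocyte markers (-0.12), presynaptic genes (0.25), chromatin regulators (0.26), stress response genes (0.14), heat shock chaperones (-0.20), neuronal cytoskeleton (0.06) and trophic receptors (0.07) lay within it in this comparison, and translation factors (-0.26) and cholesterol synthesis (-0.29) lay below it. Against the 17k library cholesterol synthesis (-0.19) was within the range, presynaptic genes (0.41) were above it and endothelial markers (-2.15, with too few members measured against 50k cells at 12.5 U/mL) below it, and against the 2.5 U/mL library corticothalamic markers (0.74) and chromatin regulators (0.42) were above it. Lists also left the range between CPN libraries, with 17k over 50k cells at 0.65 for immediate early genes, 0.52 for SCPN markers, 1.48 for endothelial markers, 0.19 for chromatin regulators, -0.40 for presynaptic genes and -0.41 for heat shock chaperones, and with 2.5 over 12.5 U/mL at 0.09 for respiratory chain genes and -0.20 for chromatin regulators.

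Among CPN footprints, counts correlated across 12856 genes at r = 0.950 between the 2 doses and across 12271 genes at 0.904 between 50k and 17k cells, against 0.889 with SCPN across 12377 genes. The share of 5' UTR counts was 12.5% (12.4 to 12.6) in CPN with 50k cells, 12.8% (12.7 to 12.9) at 2.5 U/mL, 17.6% (17.5 to 17.8) with 17k cells and 6.56% (6.50 to 6.62) in SCPN. Reads of 28 to 32 nt made up 88.3%, 48.3%, 69.97% and 82.6% of these libraries. With 1 SCPN library, no test was made.

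**Figure D3:**
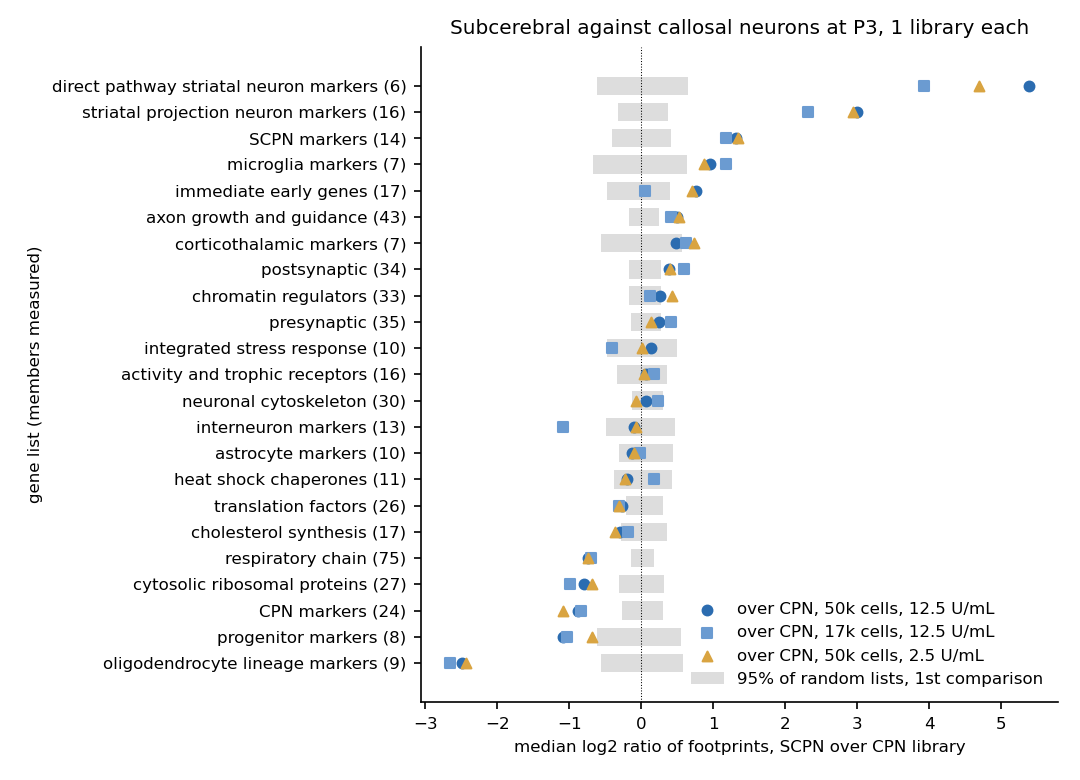
Median log2 ratio of footprints in the SCPN library over each of 3 CPN libraries (points) by gene list, with members measured in brackets and the 95% range of random lists of the same size for the comparison with 50k CPN at 12.5 U/mL (grey). SCPN markers lie at 1.17 to 1.34 and CPN markers at -1.09 to -0.84.

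In the hemispheres, footprints and RNA of the same sorts of CPN differed in where their reads lay. Coding sequence took 70.8% ± 1.78 (SD, n = 5) of region counts in footprints against 53.2% ± 0.946 in RNA, and 5' UTRs took 14.4% ± 0.341 against 5.77% ± 0.471. The 3' UTRs took 14.8% ± 1.78 against 41.1% ± 1.39. Each difference was in the same direction in 5 of 5 hemispheres and had p = 0.00794 by exact two-sided permutation, the smallest that 5 against 5 can give. Reads of 28 to 32 nt made up 83.0% ± 3.98 of footprints and 25.9% ± 1.35 of RNA, and mean lengths were 31.7 ± 0.417 and 37.3 ± 1.42 nt (exact permutation p = 0.00794 each, n = 5). No read was longer than 51 nt, a length that held 10.9% to 21.1% of RNA reads. Mean lengths are therefore of reads and not of whole fragments. With hemispheres paired, the exact sign-flip test gave p = 0.0625 for each, the smallest that 5 pairs allow.

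Relative to RNA, footprints of Atf4 and Fos were among the lowest in these sorted cells. Their libraries also held astrocyte markers at high levels, such as Fabp7 (6773 CPM in footprints, 3463 in RNA) and Slc1a3 (4962 and 2202). Values therefore describe the sorted cells as a whole, and not neurons alone. Atf4 (ENSMUSG00000042406, chromosome 15 of mm10, 80256299 to 80257457), the transcription factor of the integrated stress response, was at 45.6 ± 10.0 CPM in footprints and 293 ± 55.0 in RNA (SD, n = 5), a log2 fold change of -2.71 (SE 0.25, edgeR adjusted p = 9.58e-05). Fos (ENSMUSG00000021250), an activity-induced transcription factor, stood at -2.72 (SE 0.41, adjusted p = 0.00111). Higher in footprints were Syp (1.83, SE 0.25, adjusted p = 0.000595) and Dkk3 (1.90, SE 0.28, adjusted p = 0.00109), a secreted protein and the one CPN marker called, at 446 ± 114 CPM against 122 ± 45.2. The other largest increases were Atp5mpl (2.05), Szrd1 (1.97), Usmg5 (1.957), Ndufs3 (1.73), Sap30bp (1.69), Mllt11 (1.66), Ndn (1.65) and Dynlt1b (3.75), whose near-identical copies leave its reads uncertain. The other largest decreases were the adhesion molecule Sdk1 (-3.22), Fbxw2 (-2.85), Cenpb (-2.63), Ccni (-2.52), Tab2 (-2.49), BC005537 (-2.45), Ptp4a2 (-2.35) and Thap12 (-2.28). Some of these folds rest on few counts over 5 libraries, so their size is uncertain. Footprint counts were 29 for Ccni, 30 for Ptp4a2 and 36 for Fbxw2, and RNA counts were 13 for Dynlt1b and 18 for Szrd1. Footprints of Sdk1 (73.0 ± 70.7 CPM) and Fbxw2 (9.36 ± 11.7 CPM) also varied widely between libraries (SD, n = 5).

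Of 4224 genes tested, 731 were called, 314 higher and 417 lower in footprints. No overlap between the 5 footprint and 5 RNA libraries was seen for 514 of the called genes and for 598 of all tested, where chance gives 0.794%. The count was 446 without RNA library 1 and 463 without footprint library 1, the deepest of each kind, and 1559 with hemispheres as a block. With a trend with coding length removed, 517 genes were called, 418 of them among the 731. Against extracted RNA of P4 forebrain, 687 of 728 called genes had the same sign in the 30 ng footprints and 685 of 729 in bulk, which share that 1 RNA library. In the titration at P5 the same sign was seen for 469 of 730 called genes at 2.5 U/mL, 609 of 727 at 12.5, 564 of 730 at 62.5 and 459 of 727 at 312.5. Ratios in P4 forebrain fell with coding length (Spearman's rho -0.554 with 30 ng, -0.495 in bulk), as did those in the hemispheres. Shared signs may rest on that trend in part.

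Respiratory chain genes rose together in footprints, with 16 of 48 higher, 0 lower and 32 not called (17 higher adjusted over the list alone) and a median of 0.59. Atp5j2 (1.61) and the complex I subunits Ndufs3 (1.73), Ndufa11 (1.59) and Ndufv1 (1.06) were among them. Chromatin regulators fell together, with 15 of 31 lower, 0 higher and 16 not called (16 lower adjusted over the list alone) and a median of -0.68. The histone methyltransferase genes Ash1l (-0.92), Setd2 (-1.17) and Setd5 (-1.51) and Kmt2e (-1.57) fell. Both lists had an adjusted p of 2.00e-07 by camera and of 0.0360 with an estimated correlation. Fold changes were lower for genes with longer coding sequence (Spearman's rho -0.405 across genes). With this trend removed, the respiratory chain median was 0.14 (SD of members 0.522, before 0.525) and its adjusted p 0.119, and the chromatin median was -0.27 (SD 0.430, before 0.452) and its adjusted p 0.0419. With an estimated correlation, the adjusted p after removal was 0.418 and 0.399, so neither list was then called.

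Immediate early genes, which neurons switch on within minutes of stimulation, fell as a list, with 4 of 7 lower, 0 higher and 3 not called (5 lower adjusted over the list alone) and a median of -1.20 (adjusted p = 0.000476; adjusted p = 0.284 with an estimated correlation). Egr1 (-1.97), Nr4a1 (-1.55) and Jund (-1.20) fell beside Fos. The list has 25 members, and the 7 tested had passed a filter on counts that high RNA alone can meet. Cholesterol synthesis genes rose, with 5 of 15 higher, 0 lower and 10 not called (6 higher adjusted over the list alone) and a median of 0.47 (adjusted p = 0.00437; adjusted p = 0.284 with an estimated correlation). Msmo1 (1.35), Nsdhl (1.03), Dhcr7 (1.02) and Hmgcs1 (0.89), an early enzyme of the pathway, rose, though the call of Dhcr7 was lost in 7 of 10 fits with 1 library left out.

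Neuronal cytoskeleton genes rose, with 3 of 27 higher, 0 lower and 24 not called (3 adjusted over the list alone) and a median of 0.55 (adjusted p = 0.00829; adjusted p = 0.750 with an estimated correlation), and the tubulins Tubb2a (1.18) and Tubb4a (0.91) and the microtubule-binding kinase Dclk1 (1.04) rose. Heat shock chaperones had 1 of 9 higher, Hsp90ab1 (0.71), and 8 not called (4 higher adjusted over the list alone), with a median of 0.49 (adjusted p = 0.0458; adjusted p = 0.284 with an estimated correlation). All 10 astrocyte markers, such as the glutamate transporter Slc1a3 (1.17, adjusted p = 0.0563), were higher in footprints with 0 called, also adjusted over the list alone, and a median of 0.86 (adjusted p = 0.00876; adjusted p = 0.714 with an estimated correlation). This fit ignored pairing. Slc1a3, Aqp4, Slc1a2 and Fabp7 were each higher in 5 of 5 hemispheres. With hemispheres as a block and the preset correlation, the list had an adjusted p of 2.14e-13 by camera. That setting treats the 10 markers as nearly independent, and the block was not run with an estimated correlation. In 31 of 100 splits of the 10 libraries, the real split included, as many as the 7 lists above or more were called with the preset correlation, and the 12 others drawn that part all hemisphere pairs called at most 6. The cytoskeleton call ended without footprint library 2 (adjusted p = 0.0601 by camera) and the heat shock call without footprint library 1 (adjusted p = 0.0641).

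Translation factors went both ways, with 5 of 21 higher and 3 lower (6 and 5 adjusted over the list alone; median 0.27, adjusted p = 0.695). The elongation factor of young neurons and other cells, Eef1a1, fell by 1.25 on the log2 scale and its neuronal and muscle counterpart Eef1a2 rose by 1.33, while Pabpc1 (-1.10), which binds poly(A) tails, and Eif4g2 (-1.66) fell. Footprint reads were shorter than RNA reads, and whether both were placed equally well in these genes was not tested. Of 83 ribosomal protein genes in the counts, 13 passed the filter. Of these 13, Rps21 rose (1.59) and Rplp0 fell (-1.15), the same count adjusted over the list alone (median -0.13, mean 0.10, adjusted p = 0.715). Of 33 presynaptic genes, 3 rose, among them Syp and the vesicle GTPase gene Rab3a (0.79), and Nrxn2 (-0.72) fell (2 higher and 1 lower adjusted over the list alone; median 0.27, adjusted p = 0.190). Of 26 postsynaptic genes, 5 fell, among them the scaffold genes Dlg4 (-1.30) and Shank1 (-1.09) and the adhesion gene Nlgn2 (-1.07), and 1 rose (2 higher and 5 lower adjusted over the list alone; median -0.12, adjusted p = 0.439). Of 30 axon growth and guidance genes, Ncam1 (1.07), Dpysl2 (1.08), L1cam (1.02) and Chl1 (0.78) rose and 0 fell (3 adjusted over the list alone; median 0.08, adjusted p = 0.464). With 1 library left out, the calls of Chl1 and Rab3a were each lost in 7 of 10 fits and that of Shank1 in 5.

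Among 7 integrated stress response genes, Atf4 and the phosphatase subunit gene Ppp1r15b (-1.23) fell and 5 were not called (2 lower adjusted over the list alone; median 0.29, mean -0.31, adjusted p = 0.383). Of 15 trophic receptor genes, Bmpr1a (-1.81) fell, also adjusted over the list alone (median -0.15, adjusted p = 0.439). Of 15 CPN markers, Dkk3 rose and 14 were not called, also adjusted over the list alone (median -0.23, direction of the test up, adjusted p = 0.695). Oligodendrocyte lineage markers (9 tested, median 0.49, adjusted p = 0.181) and progenitor markers (6 tested, median 0.25, adjusted p = 0.525) had 0 calls, also adjusted over the list alone, as did the 3 SCPN, 2 corticothalamic and 3 microglia markers tested, too few for a list test. No interneuron, endothelial or erythroid marker passed the filter on counts.

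**Figure D4:**
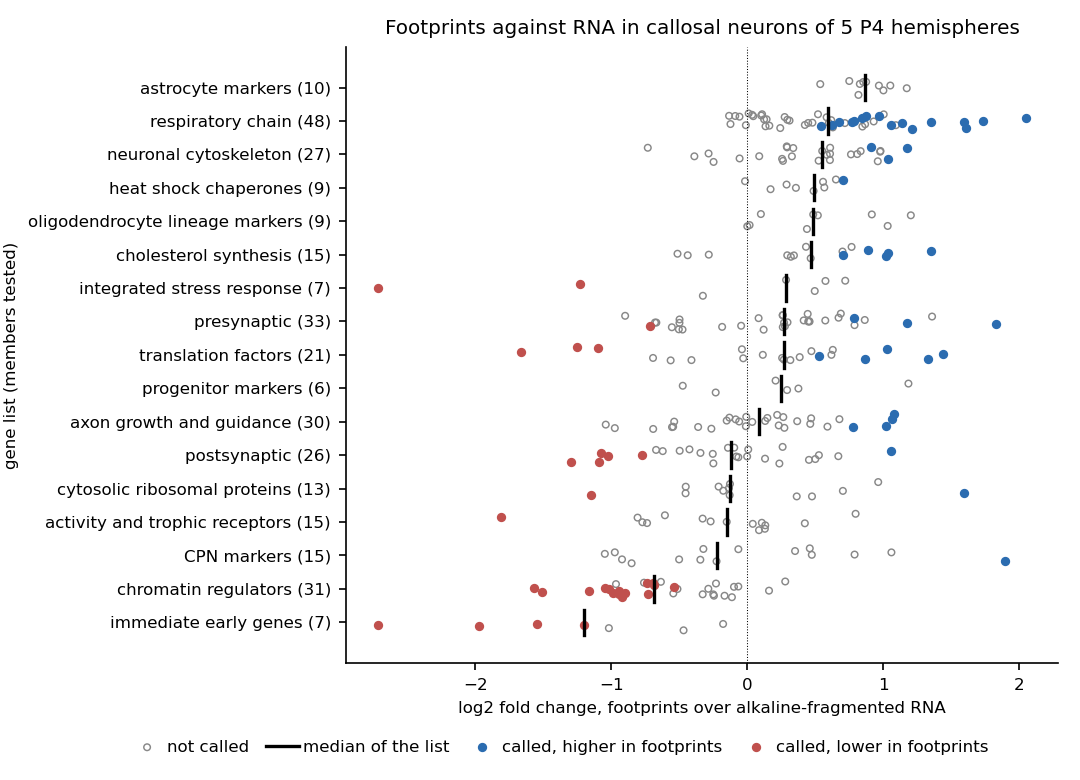
Log2 fold change of footprints over RNA in CPN of 5 hemispheres for members of each tested list (points; filled, called at adjusted p under 0.05 by edgeR) with the list's median (bars) and members tested in brackets. Immediate early genes (median -1.20) and chromatin regulators (-0.68) lie left of 0, and astrocyte markers (0.86) and respiratory chain genes (0.59) right of it.

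The authors' ORF calls located translation upstream of coding sequences. In the pooled CPN of the pilot and hemispheres, the uORF of Eif4g2 (chromosome 7 of mm10, 111082934 to 111082984, minus strand) held 333 in-frame P-sites against 381 in its coding ORF. The overlapping upstream ORF of Eif5 (chromosome 12, 111538527 to 111539679), a factor in start codon recognition, held 563 against 305, and the uORF of Ndufb10, a complex I subunit gene, 123 against 139. Fos (32 against 52), Ppp1r15b (18 against 91) and Grin2b (28 against 692), a glutamate receptor subunit gene, also carried upstream ORFs.

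Of 16151 called ORFs with 2139588 in-frame P-sites, 12390 were annotated, 1698 uORF and 517 Overlap_uORF. Upstream ORFs were called in 1758 of 11512 genes with a coding ORF (15.3%), in 2004 of 11951 (16.8%) of the CPN table and in 2293 of 12435 (18.4%) of the SCPN table, whose pooled libraries the labels do not give. The CPN and SCPN tables shared 1283 upstream ORFs by identifier, 51.2% of those of CPN and 42.6% of those of SCPN. The pilot and hemisphere table and the CPN table shared 1258, 56.8% and 50.2% of theirs. In-frame P-sites numbered 2304906 in the CPN table and 4893052 in the SCPN table, so depth and cell type cannot be told apart. In the pilot and hemisphere table, 301 of 1698 uORF and 72 of 517 Overlap_uORF had an authors' p under 0.001.

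Upstream ORFs were called in 46.7% of 30 neuronal cytoskeleton genes (adjusted p = 0.000599 by Fisher's exact test), 46.2% of 26 translation factors (0.00120), 35.3% of 34 postsynaptic genes (0.0139), 41.2% of 17 trophic receptors (0.0295), 33.3% of 33 chromatin regulators (0.0308), 31.4% of 35 presynaptic genes (0.0333) and 40.0% of 15 heat shock chaperones (0.0338), against 15.2% of other genes. In 5 bins of coding P-sites the share ran from 3.91% (3.19 to 4.78) to 30.1% (693 of 2303 genes). With genes compared within these bins, 0 of 13 lists differed in this table. Ribosomal protein genes (9.59%, adjusted p = 0.362), axon growth and guidance (27.9%, 0.0505), respiratory chain (18.1%, 0.579), immediate early (15.8%, 1), integrated stress response (20.0%, 0.711) and cholesterol synthesis genes (21.1%, 0.612) did not differ without the bins either. Cytoskeleton and postsynaptic genes also differed in the CPN table (53.3% and 38.2%) and the SCPN table (43.3% and 50%), translation factors (42.3%) and trophic receptors (62.5%) in the CPN table, and presynaptic genes (45.7%) and heat shock chaperones (46.7%) in the SCPN table. Within bins, cytoskeleton (adjusted p = 0.0243) and trophic receptor genes (0.0153) stayed above others in the CPN table, and ribosomal protein genes were below others in the CPN (0.0222) and SCPN (0.0191) tables.

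Genes with an upstream ORF were not called lower than others in the hemisphere contrast, though this turned on the setting. Their median log2 fold change was -0.05 over 1089 genes against 0.05 over 3106 others (camera p = 0.104, reached by 42 of 100 splits in a permutation of the libraries), with a lower median in 5 of 5 hemispheres, by 0.06 to 0.13 (from -0.10 to 0.01 against genes matched on RNA counts), and 78 were called higher and 140 lower. The median difference was -0.15 for uORF alone and -0.14 with the trend with coding length removed, both under the 0.05 threshold of camera, and -0.05 against matched genes, which was not. With 1 library left out, camera passed that threshold in 3 of 10 fits, without footprint library 1, footprint library 2 or RNA library 3. These upstream ORFs were called on pooled footprints that included those of the hemispheres, and more often in genes with more coding P-sites. The set thus depends on the footprints tested here. For that reason the comparison cannot decide whether genes with an upstream ORF have a lower ratio.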

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

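All tests of explanations in this part were chosen after the results were seen.

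Immediate early transcripts were low in footprints of sorted CPN while their RNA was high in the same sorts, which also held astrocyte markers. In RNA, the 7 tested members had a median log2 ratio over P3 cortex RNA, relative to all tested genes, of 0.62 to 2.13 in the 5 hemispheres, with Fos at 517 ± 232 CPM (SD, n = 5) against 71.3. Transcription during dissociation while cycloheximide held translation may account for the low ratio. The RNA values cannot settle this, since 7 of 25 members passed the filter on counts, which high hemisphere RNA alone can meet. Jund, for example, was at 49.3 CPM in footprints and 113 in RNA. Forebrain cannot test it either, since the same members had 0 to 15 counts in its RNA library. A trend with coding length is argued against, since the median of these 7 members went from -1.20 to -1.45 with that trend removed. The SD of members was then 0.894, and the adjusted p by camera was 1.17e-05, or 0.374 with an estimated correlation. A lower translation of these messages in CPN, the mix of cell types in the sort, the ages and the dissection of the cortex library stay open, untested.

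Respiratory chain genes were high and chromatin regulators low in the same footprints. Against RNA cut with RNase I, respiratory chain medians were above random lists in all 6 forebrain footprint libraries (0.46 to 1.16), which argues against cutting by alkali as the whole cause for that list, while chromatin medians were below them in 4 and within them at 2.5 and 312.5 U/mL of the titration (-0.0358 and 0.0555), so for that list cutting by alkali and other causes cannot be told apart. With the trend with coding length removed, the respiratory chain median was 0.14 (SD 0.522) and its call ended because the members moved toward 0, so the trend may account for that list. For the chromatin regulators, the trend and a change of their own cannot be told apart, since the list was called with 1 correlation and not the other. Their median was -0.27 (SD of members 0.430), and the adjusted p by camera was 0.0419 with the preset and 0.399 with an estimated correlation. The trend may be of ribosome loading or of library preparation, and no biological explanation was tested.

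The SCPN pilot library held striatal transcripts, such as Tac1, a neuropeptide gene, with 106 counts against 3 in CPN with 50k cells, and Pdyn with 59 against 5. Direct pathway striatal neurons, whose axons run toward the cerebral peduncle where the tracer was injected, are a candidate source that cannot be told apart from others, since the median log2 ratio of their 6 measured markers, at least 3.92 over each of 3 CPN libraries, comes from a list written after these values were seen and restates the pattern. Indirect pathway markers made up 2.42% (1.18 to 4.91) of direct and indirect pathway counts in SCPN, against 48.0% (39.3 to 56.7) in forebrain footprints. Without Tac1 and Pdyn the shares were 5.65% (2.76 to 11.2) and 77.6% (67.1 to 85.5). Both lists were written after values of the SCPN library were seen. Penk held 26 (30 ng) and 21 (bulk) of the 59 indirect counts in forebrain, which is not striatum alone. Carry-over of striatal neurons of every kind therefore looks less likely but cannot be excluded. Of the 18 members of the striatal list, 8 had 10 or more counts in CPN with 50k cells and 1 is also a fixed corticothalamic marker. A sort on the tracer would remove unlabelled striatal cells, and expression of these genes in SCPN themselves stays open, untested.

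Groups of 5 libraries were examined for named genes, region shares and read lengths. Of 180 such groups, 11 (6.11%), all of named genes, had 1 library far from the other 4, where chance gives about 5%. In footprints these were Dynlt1b in hemisphere 1 (log2 CPM 8.40, others 7.54 to 7.72), Thap12 (0.89, others 4.90 to 6.05), Pabpc1 (8.83, others 8.24 to 8.36) and Setd5 (4.72, others 6.80 to 7.34) in hemisphere 3, and Slc3a2 (8.73, others 8.06 to 8.21) and Ntrk3 (7.25, others 7.80 to 8.02) in hemisphere 5. In RNA they were Ndufv1 in hemisphere 1 (8.17, others 7.42 to 7.58), Fos (7.42, others 9.29 to 9.88) and Atp5j2 (7.19, others 6.06 to 6.36) in hemisphere 2, Tubb4a in hemisphere 3 (8.735, others 9.30 to 9.37) and Dnajb4 in hemisphere 4 (6.93, others 6.27 to 6.36).

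Tbr1, a corticothalamic transcription factor, was higher in footprints than RNA in 5 of 5 hemispheres (0.17 to 1.09, edgeR log2 fold change 0.47, adjusted p = 0.301), but at -0.83 (-1.60 to -0.04) in 30 ng forebrain and -0.84 in bulk, which share 1 RNA library, and the difference was not tested. In classes of reads outside the gene counts, 28 to 32 nt made up 43.6% ± 5.16 of lincRNA reads in hemisphere footprints against 28.3% ± 2.69 in RNA, and 58.5% ± 3.63 of snoRNA reads against 26.5% ± 2.68 (SD, n = 5, exact permutation p = 0.00794 each). That test ignores pairing. A paired sign-flip test was not run here, and 5 pairs allow it no p under 0.0625.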

How the results depend on the processing

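Removal of the length trend, omission of hemisphere 3, tests of upstream ORF genes by type and with an estimated correlation, the paired test of lengths and the 5' UTR alternatives were chosen after the data were seen. Over these and the others, 144 alternative values of the comparisons kept their direction and side of the threshold or stayed within the spread or 1.5 times the count, 38 moved, 5 gained and 6 lost a call. For lists the numbers were 257 kept, 5 gained and 10 lost, and for the named genes reported here 981 kept, 42 gained, 33 lost and 7 reversed. The cause of changes was not tested except where stated. CPN against SCPN replicates, HEK293T cells and omission of mitochondrial genes were not run.

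In the hemispheres, 1559 genes were called with the replicate block, 126 against a 1.5-fold threshold, which asks for more by construction, and 446 (without RNA library 1) to 824 (without footprint library 3) with libraries left out. With the length trend left in, the block changed no list call and lost no named gene. With the trend removed, it added calls by camera for ribosomal protein and presynaptic genes (adjusted p 0.0525 to 0.0415 each) and axon growth and guidance (0.0525 to 0.00606). All 57 called named genes were kept by RLE factors and DESeq2, and 50 to 55 with 1 library left out. In these 10 fits the calls of Chl1, Rab3a and Dhcr7 were lost in 7, of Shank1 in 5, of Nrxn2 and Nsdhl in 3, of Sap30bp in 2 and of L1cam in 1. An estimated correlation left 2 of 7 lists and fry called 5. The exact paired test gave p = 0.0625, its smallest, for coding (17.6%), 5' UTR (8.67%) and 3' UTR (-26.3%) differences and for mean length (-5.64 nt), commonest length (-20.2 nt) and 28 to 32 nt (57.0%). RNA reads were commonest at 51 nt, the longest read, so differences in mean and commonest length are of reads and not of whole fragments. With 1 library left out, log2 fold changes ran from -0.32 to 0.35 for Tle4 and -0.54 to 0.71 for Csf1r, neither of them called.

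Without the 10 most abundant genes, coding shares were 57.1%, 73.2%, 68.1% and 59.3% from 2.5 to 312.5 U/mL. At 27 to 33 nt, shares were 48.3%, 84.9%, 71.7% and 50.5%, and 24.1% in extracted RNA. With at least 10 and 100 counts, r was 0.932 and 0.937 for 30 ng and bulk, 0.702 and 0.483 for 30 ng and extracted RNA, and 0.661 and 0.523 for bulk and extracted RNA. For CPN with 50k cells it was 0.964 and 0.975 with the other dose, 0.912 and 0.898 with 17k cells, and 0.879 and 0.852 with SCPN.

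Within bins of P-sites, 0 lists differed in upstream ORFs in the pilot and hemisphere table and 1 in the SCPN table. With the authors' p under 0.001, 0 differed in the CPN table and 2 in the SCPN table. Counted by gene, tables shared 46.2% (pilot and hemispheres with CPN), 41.3% (with SCPN) and 41.0% (CPN with SCPN) of the union. For upstream ORF genes the median difference was -0.15 for uORF alone and -0.14 without the length trend, both under 0.05 by camera, and with libraries left out it ran from -0.13 (without footprint library 1) to -0.0697 (without footprint library 5). Depth limits which genes can be tested, since 4224 of 20866 passed the filter on counts. In simulated data of the same size 31.0% of 2-fold changes were recovered, and depth, spread and n were not varied apart.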

Other observations

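The 5' UTR fit and its tests, and the tests of other splits, were chosen after the data were seen, and the genes named from the fit after their values were seen.

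Footprints of hemisphere CPN were higher in the 5' UTRs of many genes that could be tested on the scale of coding counts. In Eif5, whose product aids start codon recognition, 5' UTR footprints were higher than RNA by 2.12 on the log2 scale (SE 0.38, edgeR adjusted p = 0.000434), while its coding sequence stood at -0.41 (adjusted p = 0.191). Of 426 genes tested, 232 rose, 10 fell and 184 were not called. On this scale a shift of all 5' UTRs enters every gene. As a whole, 5' UTRs took 14.4% of region counts in footprints against 5.77% in RNA. Calls relative to the average 5' UTR were not made. The share was 8.86% in 30 ng and 7.47% in bulk forebrain footprints. It was 6.56% in the SCPN pilot, whose cycloheximide was added only after the sort. A part of the drug in these counts was not tested. In 8 genes the 5' UTR rose while the coding sequence fell. Among them were Eif4g2 (1.56 against -1.66), the activity-induced receptor gene Nr4a1 (1.62 against -1.55), Tnrc6a of microRNA silencing (3.15 against -1.48), Ptp4a2 (1.25 against -2.35), Rnf10 (1.38 against -2.06), the Wnt receptor gene Fzd3 (1.00 against -1.02) and the GABA receptor gene Gabbr1 (1.46 against -0.59). The fit called 301 genes with hemispheres as a block and 207 of 421 tested (without footprint library 1) to 358 of 631 (without RNA library 3) with 1 library left out. Of 100 splits of the 10 libraries, 1, the real one with 242 genes, gave as many, and the highest other called 5. Most of these put both libraries of some hemispheres on 1 side, unlike the real one. The 12 others that part all hemisphere pairs called 0, and are too few for a share under 0.05, so the splits cannot exclude chance.

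For the 731 genes of the coding fit, 1 of 100 splits, the real one, called as many. The highest other called 208, with 3 footprint libraries on the side of hemisphere 1 and 1 pair parted, and the next 19. Of the drawn splits that, like the real one, part all pairs, 12 others called at most 0 genes. Most of the 100 splits put both libraries of some hemispheres on 1 side, unlike the real one, and libraries of a hemisphere are alike. Those that part all pairs are too few for a share under 0.05, so the splits cannot exclude chance. For the 7 lists called with the preset correlation, 31 of 100 splits called as many and the highest other called 10, so over all splits chance cannot be excluded for their number. The 12 others that part all pairs called at most 6, and are too few for a share under 0.05. With the estimated correlation, 1 of 100 splits, the real one with 2 lists, called as many and the highest other called 0. Those that part all pairs are again too few, so the splits cannot exclude chance here either. For genes with an upstream ORF, 42 of 100 splits gave a p as small as 0.104, the smallest of the others being 0.000221, so over all splits chance cannot be excluded. Among the 12 that part all pairs the smallest was 0.144, and they are again too few.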
